A study of Mus musculus with 18 samples.

How the data were processed

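The authors deposited 1 table of gene counts per library, and the unit of these deposited values is counts, per the file headers. Per the labels' protocols, B6;D2-Tg(S100B-EGFP)1Wjt/J mice were injected intraperitoneally once a day for 14 days, with clozapine given at 10 mg/kg and risperidone at 1 mg/kg. Per the labels' protocols, CD45, Thy1 and HepaCAM antibodies captured microglia, neurons and astrocytes in sequence after depletion of endothelial and oligodendrocyte lineage cells. Per the labels' protocols, RNA was extracted with a Viogene miniprep kit, and libraries were made from 20 ng total RNA with QIAseq FastSelect removal of ribosomal RNA, random hexamers and oligo-dT. Per the labels' protocols, libraries were sequenced as paired ends on a NextSeq 2000. Per the submitters' processing notes, reads were checked with FastQC. Per the file headers, featureCounts v2.0.8 counted reads over exons by gene identifier with multiple overlaps allowed (-O) and without a strand setting, on GRCm39. The aligner is not given in the sources used here. Counts of genes that overlap, lie antisense to each other or share reads are therefore uncertain.

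Reads assigned per library ranged from 4.71 to 13.39 M, with a median of 7.44 M. The most abundant gene took at most 2.24% of a library and the 10 most abundant 6.54 to 11.9%, and protein-coding genes took 83.5 to 89.9%. Gene names and biotypes came from GENCODE vM21 by gene identifier, which covered 52029 of 56953 identifiers and 96.2% of counts; coordinates are those in the file headers. A combined table keyed by gene symbol was not used, since its totals equal those of the single tables, which keep the identifiers. The 37 mitochondrial features had 0 counts in all 18 libraries, so mitochondrially encoded genes could not be examined. Labels give male and female mice in 1 place and adult males in another. Xist and the Y-linked gene Ddx3y were found in all 18 libraries, so the pools held both sexes, and sex was not used in the fits.

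Tests ran in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Each fraction was fitted alone with 6 libraries, the 3 vehicle groups together with 6, and interactions with all 18. Genes passed filterByExpr (32846 in microglia, 31022 in astrocytes, 25510 in neurons, 29696 in vehicle, 37310 in all), and libraries were scaled by TMM. The edgeR quasi-likelihood test without a block gave p, adjusted by Benjamini-Hochberg, and genes or lists under 0.05 were called. Residual degrees of freedom were 3 per fraction and 9 in all, and the biological coefficient of variation was 0.356 in microglia, 0.499 in astrocytes and 0.472 in neurons. SE is the absolute log2 difference divided by the square root of the F statistic. Leaving out 1 library leaves its group with 1, assumed to vary like the others. Fits with a library left out carry no batch term, so the difference between batches enters comparisons with that group. Changes seen there can reflect the batch as well as the library.

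Before the data were examined 51 gene lists of cell types and functions were fixed, and 50 had at least 5 tested members. They were tested with camera at a preset correlation of 0.01 on log2 CPM with a prior count of 2, beside camera with an estimated correlation and fry. The option that lets the prior variance follow expression was switched on in camera, which the fixed plan does not mention. The comparisons, lists, thresholds and alternatives were likewise set before the data were examined. Alternatives were the replicate block, DESeq2, RLE scaling, no low-count filter, adjusted p under 0.10, an absolute log2 difference of at least 1, each library left out, and all 18 libraries in 1 fit. A covariate for the markers of another cell type, the leave-1-out test of every called list, the drug correlations with separate vehicle pools or a library left out of the simulation or among abundant genes of the simulation, and the interactions with each of the 6 pools as a block (6 residual degrees of freedom), were added after values were seen.

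Genes were named by a rule set before the data were examined. For each drug against vehicle it took up to 10 called genes per direction that changed the same way in both batches, and with fewer than 5 it filled to 5 with those of smallest p. Between drugs and for interactions 5 or 3 were taken, and between fractions 5. Unnamed, predicted and pseudogenes were skipped in naming only. Members of called lists tested under the alternatives were limited to the 6 lists with the smallest p for each drug against vehicle and 3 between drugs. They were limited to 3 members each, and this limit was chosen after values were seen. Bst2, P2ry12 and Gabrg3 in risperidone microglia, Ptprb and Tnf in clozapine astrocytes, Penk in risperidone astrocytes, and Col1a1 and Hbb-bs in clozapine neurons are printed from other called lists. These genes were not tested under the alternatives. Only part of the genes under the rule are printed, and results of some genes are not reported here and were left out of the alternatives. Gm36264, the unnamed genes and the genes called only with the replicate block lie outside the rule and were chosen after values were seen.

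Pairing by replicate number comes from the labels, in which the number is also the batch. Correlations of the batch 1 minus batch 2 differences between treatments were 0.17, 0.13 and 0.12 in microglia, 0.20, 0.53 and 0.27 in astrocytes and 0.18, 0.55 and 0.25 in neurons (vehicle with clozapine, vehicle with risperidone, clozapine with risperidone). Within the 9 groups no replicate duplicated the other, with a chi-square per degree of freedom of 11.8 to 48.8. Other pairs of libraries were not compared. Tests of other explanations for the interferon-stimulated and oxidative phosphorylation genes were first made against the spread between vehicle pools and in batch 1 alone. They were replaced, after those values were seen, by a linear model of list means with batch as a term, and a floor of 3 mean log2 CPM for leukocyte markers was set then too.

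The pipeline was tested on simulated data with 200 changed genes, and on 20 simulations per fraction for the drug correlations. Changed genes were drawn from those at a mean of 8 CPM or more, with 67 at 2-fold and 67 at 4-fold. Recovery of genes below that level was not tested. For clozapine without a block, 4-fold changes were recovered for 65.7% of these changed genes in microglia (30550 genes tested), 43.3% in astrocytes (27474) and 62.7% in neurons (22858), and 2-fold changes for 2.99%, 0% and 2.99%. With the replicate block 2-fold changes were recovered for 32.8%, 16.4% and 19.4% in the same order. A list raised 1.5-fold had a camera adjusted p of 3.19e-10, 4.33e-08 and 0.000151 in the 3 fractions at the preset correlation. Its adjusted p was 0.216, 0.3 and 0.624 with an estimated correlation, so that test would miss a true shift of this size with 2 libraries per group. With fry the adjusted p was 0.000255, 0.194 and 0.0177, which recovers the list in microglia and neurons and misses it in astrocytes. Genes were simulated independently of each other. These values therefore do not show how often the preset correlation calls lists of correlated genes.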

Results

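RNA was sequenced from microglia, astrocyte and neuron fractions immunopanned from mouse frontal cortex after 14 daily injections of vehicle, clozapine at 10 mg/kg or risperidone at 1 mg/kg. Each pool held the cortices of 5 animals and each treatment had 2 pools, so the 18 libraries form 9 groups of n = 2. The microglia libraries held 7.01 and 8.17 M assigned counts with vehicle, 7.40 and 9.53 M with clozapine, and 5.28 and 6.26 M with risperidone. Astrocyte libraries held 6.32 and 5.12 M, 7.47 and 9.21 M, and 10.65 and 4.71 M in the same order. Neuron libraries held 6.88 and 11.38 M, 11.25 and 13.39 M, and 6.52 and 12.26 M. Replicate numbers name the batch, and values within batch 1 and batch 2 are given in that order. Differences are log2 fold changes with their standard error (SE), levels are counts per M (CPM), and adjusted p is the Benjamini-Hochberg value over all genes or all lists tested.

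The first question was how far each fraction was enriched for its cell type. Cx3cr1, the microglial fractalkine receptor, averaged 401 CPM (SD 122, n = 6 libraries) in the microglia fraction, 34.4 (SD 12.5) in the astrocyte fraction and 25.3 (SD 27.4) in the neuron fraction. Aqp4, the astrocyte water channel, averaged 74.2 (SD 24.9), 321 (SD 92.2) and 132 (SD 42.1) CPM in the same order. Rbfox3, a neuronal splicing factor, averaged 84.4 (SD 50.8), 113 (SD 42.8) and 309 (SD 76.5) CPM. Snap25, a synaptic fusion protein, averaged 1720 (SD 677) in neurons and still 517 (SD 418) in microglia. Mbp, which encodes myelin basic protein, averaged 9900 (SD 10374) in astrocytes and 6713 (SD 6029) in neurons against 300 (SD 110) in microglia. The endothelial tight-junction gene Cldn5 lay between 0.238 and 7.89 CPM in every library. Other cell types therefore contributed RNA to each fraction, and their levels are given beside the gene groups. Xist, expressed from the inactive X of females, lay between 119 and 557 CPM, and the Y-linked gene Ddx3y between 23.7 and 104 CPM, in all 18 libraries, so every pool held both sexes. In replicate 2, Xist stood at 305, 150 and 119 CPM with vehicle and 503, 369 and 261 with risperidone (microglia, astrocytes, neurons). Ddx3y stood at 90.2, 36.9 and 43.9 against 63.1, 23.7 and 26.5. In replicate 1 neither gene differed between risperidone and vehicle in the same direction in all 3 fractions. With clozapine Xist was higher than with vehicle in both replicates of all 3 fractions, as in microglia replicate 1 at 557 against 371 CPM. Ddx3y was also higher with clozapine in replicate 2 of all 3 fractions, but in replicate 1 only in microglia. Camera called sex-linked genes for clozapine in astrocytes and between drugs in microglia. Neither call held with an estimated correlation. Sex was not in the fits, so pools of unlike sex balance cannot be told apart from a drug effect.

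**Figure D1:**
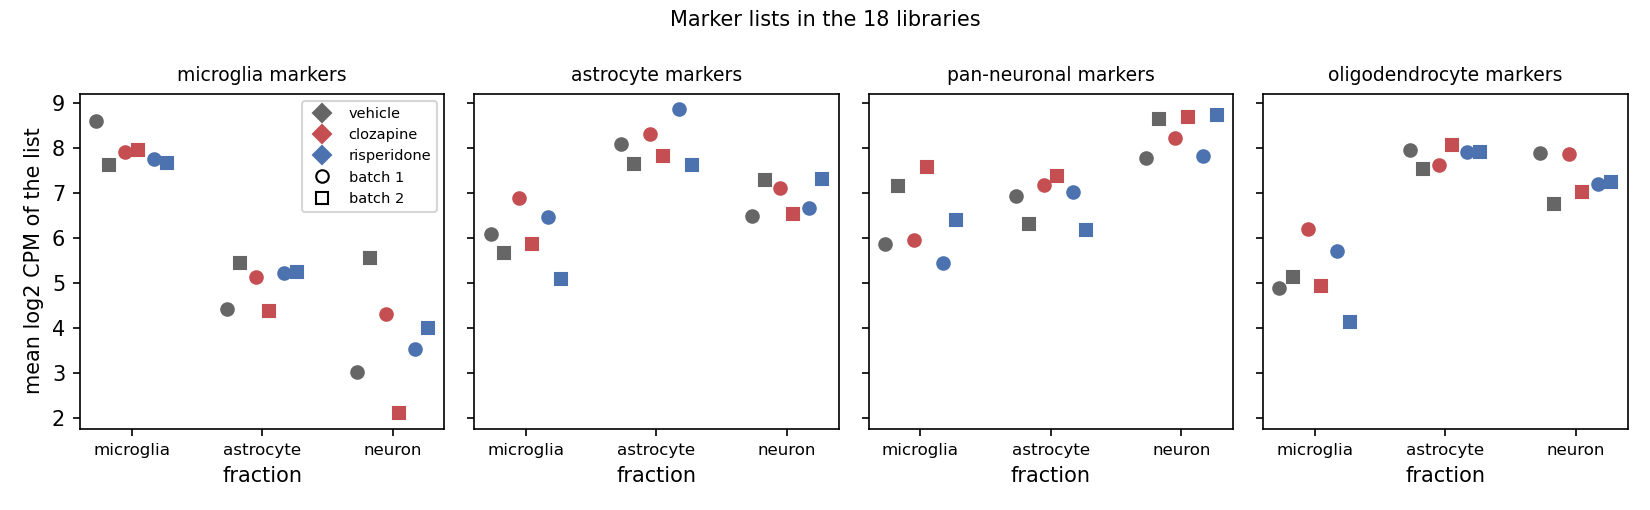
Mean log2 CPM of marker lists in each library by fraction. Microglia markers ranged from 7.62 to 8.59 in the microglia fraction, and in the neuron fraction they reached 5.55 in vehicle replicate 2 and 2.10 in clozapine replicate 2.

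In vehicle animals microglia were compared with astrocytes to ask which genes separate the fractions (n = 2 against 2). Tmem173, which encodes the DNA-sensing adaptor STING, was higher in microglia by 3.30 (SE 0.55), at 79.3 and 44.5 CPM against 2.73 and 9.22. Samsn1, a signalling adaptor of blood cells, was higher by 3.23 (SE 0.55), and Hba-a2, a haemoglobin gene, by 6.28 (SE 0.96), at 541 and 37.2 CPM against 3.53 and 3.79, and by 3.25 without microglia vehicle replicate 1. Fabp7 (ENSMUSG00000019874.12, chromosome 10, 57660977 to 57664546), a fatty acid carrier of astrocytes, differed by −3.69 (SE 0.52), at 7.54 and 8.34 CPM against 148 and 56.4. Serpinb1a, a protease inhibitor, differed by −3.20 (SE 0.53), and Ppp1r14a, a phosphatase inhibitor, by −2.95 (SE 0.46). Of 20 microglia markers 14 were called higher, with a list median of 3.20, while 17 of 20 oligodendrocyte markers (median −2.83) and 7 of 20 astrocyte markers (median −1.95) were called lower. None of the 20 pan-neuronal markers was called (median −0.03), and 5 of 7 erythrocyte genes were higher. edgeR called 715 genes at adjusted p under 0.05, 472 higher and 243 lower, with adjusted p = 0.0171 for each gene named here. The replicate block gave 1446 and DESeq2 1349. The count was 97 without astrocyte vehicle replicate 1, 1459 without astrocyte vehicle replicate 2, 1424 without neuron vehicle replicate 1 and 1374 without neuron vehicle replicate 2.

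Microglia were compared with neurons in the same animals to ask what sets these fractions apart (n = 2 against 2). Rhoh, a small GTPase of blood cells, was higher in microglia by 3.65 (SE 0.49), at 55.7 and 29.8 CPM against 4.39 and 2.13. Fgd2, a regulator of Cdc42, was higher by 3.51 (SE 0.51). Akr7a5, an aldehyde reductase, differed by −3.79 (SE 0.53), at 10.1 and 8.11 CPM against 147 and 90.4. Of 20 microglia markers 16 were called higher (median 3.38), and 6 of 20 pan-neuronal markers (median −1.72) and 16 of 20 oligodendrocyte markers (median −2.64) were called lower. Nuclear-encoded oxidative phosphorylation genes, which build the respiratory chain, were lower in microglia for 11 of 31 members (median −1.25). edgeR called 1810 genes, 929 higher and 881 lower, with adjusted p = 0.00929 for Rhoh and Akr7a5. The replicate block gave 2988 and DESeq2 3143. The count was 616 without microglia vehicle replicate 1, 3375 without neuron vehicle replicate 1, and 3065 and 3270 without astrocyte vehicle replicate 1 and 2.

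Astrocyte and neuron fractions of vehicle animals were compared next, to ask how well the later panning steps were separated (n = 2 against 2). Gm36264, a long noncoding RNA of unknown function, was lower in astrocytes, at −6.55 (SE 0.86), with 12.7 and 4.47 CPM against 1290 and 263. Akr7a5 differed by −3.19 (SE 0.51) and the chloride channel accessory gene Clca3a1 by 4.47 (SE 0.74), each with adjusted p = 0.116 in edgeR. Pan-neuronal markers had a median of −1.81 and astrocyte markers 0.83, and no member of any fixed list was called. Gm36264 was the only gene called by edgeR (adjusted p = 0.0172), although 4854 genes had an unadjusted p under 0.05. With the replicate block 64 genes were called, among them Clca3a1 (edgeR adjusted p = 1.02e-07) and Akr7a5 (edgeR adjusted p = 7.64e-06), and DESeq2 called 490. The count was 1100 without neuron vehicle replicate 1, 5 without neuron vehicle replicate 2, 33 and 8 without astrocyte vehicle replicate 1 and 2, and 37 and 70 without microglia vehicle replicate 1 and 2.

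The next comparison asked which genes differ in microglia after clozapine (n = 2 against 2). The interferon-induced genes Oasl1, Ifit2, Ifit1 and Rsad2, which encode antiviral effectors, read higher with clozapine in both batches. Oasl1 (ENSMUSG00000041827.16, chromosome 5, 115061299 to 115075974) stood at 306 and 149 CPM against 126 and 28.6 with vehicle, a difference of 1.54 (SE 0.76; 1.28 and 2.34 within batches). Ifit2 (ENSMUSG00000045932.13) stood at 65.8 and 45.7 against 28.5 and 5.56 (1.70, SE 0.74), and Ifit1 (ENSMUSG00000034459.9) at 115 and 46.2 against 53.9 and 3.59 (1.48, SE 1.03). Rsad2 (ENSMUSG00000020641.17) stood at 111 and 41.3 against 49.2 and 10.5 (1.34, SE 0.79). None of the 4 passed edgeR without a block (adjusted p = 1). With the replicate block all 4 rose, by 1.86 for Oasl1 (edgeR adjusted p = 0.0157), 2.13 for Ifit2 (0.033), 2.30 for Ifit1 (0.035) and 1.56 for Rsad2 (0.0466). The unblocked differences moved with single libraries left out, in fits without a batch term, so the batch difference enters them. Without vehicle replicate 1 they were 3.01 for Oasl1, 3.33 for Ifit2, 4.50 for Ifit1 and 2.87 for Rsad2, and without vehicle replicate 2 0.83, 0.95, 0.57 and 0.62. Without clozapine replicate 1 they were 0.88, 1.36, 0.62 and 0.40. The fifth blocked call, the unnamed gene ENSMUSG00002075676.1 on chromosome 12, differed by 2.48 (SE 0.38; 1.97 and 3.04 within batches), with an edgeR adjusted p of 0.819 unblocked and 0.000298 blocked. Among the remaining genes with the smallest p, Abhd17a, a depalmitoylating enzyme, differed by 1.16 (SE 0.34) and the noncoding RNA Rny1 by 2.06 (SE 0.52).

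edgeR called 0 genes for clozapine in microglia, with 1040 at an unadjusted p under 0.05, against 5 with the replicate block and 1 in DESeq2, the unnamed chromosome 12 gene. The count was 1 without microglia clozapine replicate 1. In simulated data of 30550 genes the unblocked test recovered 2.99% of 67 genes changed 2-fold and 65.7% of 67 changed 4-fold. These genes all lay at a mean of 8 CPM or more, and even there most differences of 2-fold or less would be missed. Oligodendrocyte markers had a median of 0.70 in this comparison and astrocyte markers 0.59.

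**Figure D2:**
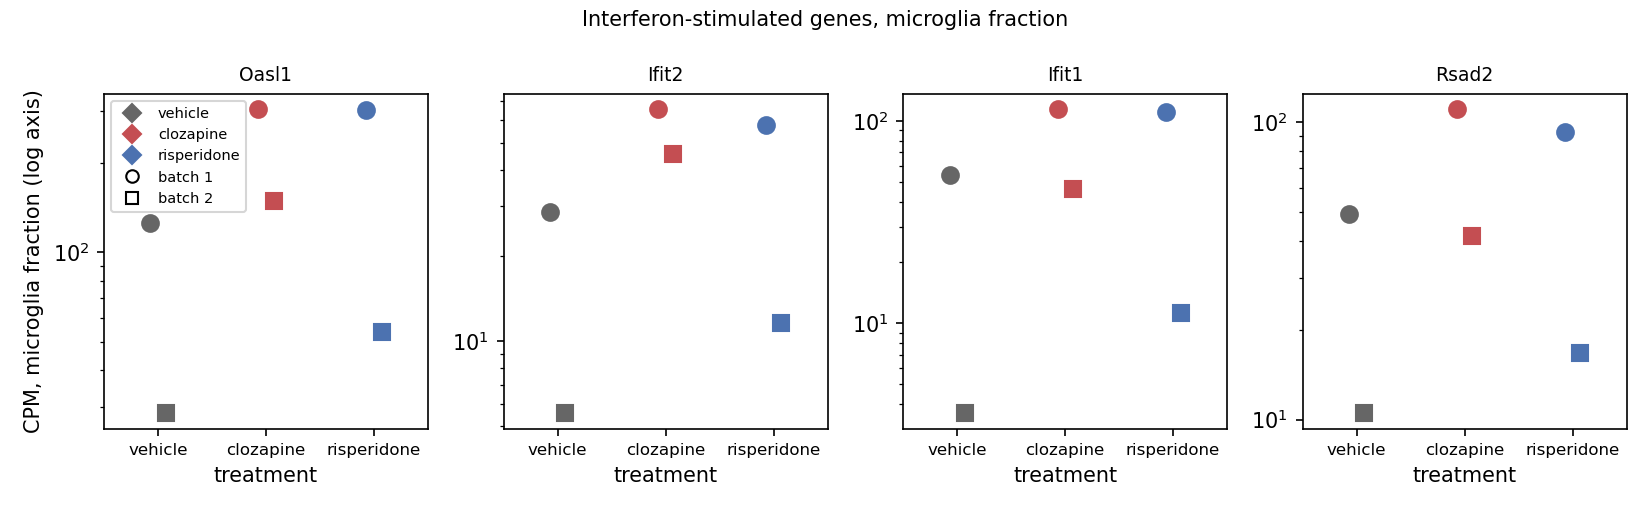
CPM of Oasl1, Ifit2, Ifit1 and Rsad2 in each microglia library. Oasl1 stood at 306 and 149 with clozapine, 304 and 54 with risperidone and 126 and 28.6 with vehicle.

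Gene groups in clozapine microglia were then tested to ask whether functions shift together. Oxidative phosphorylation genes were higher for 31 of 31 members, with a median of 0.46 (0.29 and 0.62 within batches), as in Ndufb9 of complex I at 1.11 (SE 0.44) and Atp5c1 of the ATP synthase at 0.63 (SE 0.30). Interferon-stimulated genes were higher for 23 of 27, with a median of 0.54 (0.43 and 0.97), including the antiviral GTPase Mx2 at 1.14 (SE 0.41) and the regulator Irf7 at 1.07 (SE 0.43). Dissociation response genes, induced during tissue handling, were lower for 23 of 26 with a median of −0.50 (−0.79 and −0.00), as in Fosb at −1.31 (SE 0.43). Oligodendrocyte markers were higher for 20 of 20 (median 0.70; 1.35 and −0.11), for example the myelin enzyme Cnp at 1.24 (SE 0.57). Ribosomal protein genes were higher for 30 of 33 (median 0.24; −0.10 and 0.72), as in Rpl4 at 0.49 (SE 0.33). Camera adjusted p was 4.09e-09 for oxidative phosphorylation, 5.73e-08 for interferon-stimulated, 9.66e-06 for dissociation, 7.83e-05 for ribosomal and 0.000144 for oligodendrocyte genes. Each of these calls was lost, at adjusted p = 0.994 with an estimated correlation. Without vehicle replicate 2 the camera adjusted p of interferon-stimulated genes was 0.253 and that of ribosomal genes, then lower, 0.214. Without vehicle replicate 1 dissociation genes had a camera adjusted p of 0.797, and without clozapine replicate 1 oligodendrocyte markers were lower at 0.763.

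Camera called 14 of 50 lists for clozapine in microglia, 12 higher and 2 lower, with the preset correlation, 20 with the replicate block and 0 with fry, whose smallest adjusted p was 0.997. Only oxidative phosphorylation stayed called with each of the 6 libraries left out, where its highest camera adjusted p was 0.00383. The count was 28 without vehicle replicate 1, 24 without vehicle replicate 2 and 25 without clozapine replicate 2. No list member was called over all genes; adjusted over the list alone 2 were, and 32 with the replicate block, 10 of them interferon-stimulated. Microglia markers had a median of −0.23 (camera adjusted p = 0.134, and 0.0241 with the replicate block), blood leukocyte markers −0.36 (0.108), and pan-neuronal markers 0.33 (0.0794, and 0.00256 with the replicate block). With the block and an estimated correlation these 2 blocked calls were lost, at camera adjusted p of 0.821 for microglia and 0.82 for pan-neuronal markers.

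Risperidone was compared with vehicle in microglia to ask which genes answer to this drug (n = 2 against 2). Jun (ENSMUSG00000052684.5, chromosome 4, 94937271 to 94940459), an immediate-early transcription factor, stood at 257 and 293 CPM against 1105 and 468, a difference of −1.40 (SE 0.39; −1.96 and −0.57 within batches). Txnip, a brake on glucose uptake, stood at 70.6 and 82.4 against 295 and 146 (−1.41, SE 0.37; −1.91 and −0.71). Without vehicle replicate 1, which also had the highest mean of dissociation response genes among the microglia libraries (8.60 log2 CPM against 7.43 to 7.75), Jun differed by −0.66 and Txnip by −0.82. Mlycd, which degrades malonyl-CoA, stood at 11.6 and 14 against 31.8 and 34.6 (−1.25, SE 0.32; −1.30 and −1.19). Psmb11, a thymic proteasome subunit, differed by 1.78 (SE 0.41) and Chrng, an acetylcholine receptor subunit, by 2.06 (SE 0.49). All 5 had an edgeR adjusted p of 0.929. edgeR called 0 genes, with 1407 at an unadjusted p under 0.05, and the replicate block and DESeq2 also called 0. The count was 1 without microglia vehicle replicate 1.

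Among gene groups in risperidone microglia, dissociation response genes were lower for 22 of 26, with a median of −0.48 (−0.73 and −0.18 within batches), including the immediate-early genes Fos at −1.20 (SE 0.42) and Fosb at −1.13 (SE 0.43). Activity-regulated genes, which overlap with them, were lower for 19 of 23 (median −0.41; −0.35 and −0.30), as in the phosphatase gene Dusp6 at −0.97 (SE 0.40). Neuronal transcripts read lower too: voltage-gated channels for 20 of 21 (median −0.56; −0.43 and −0.66), GABA receptors for 14 of 14 (median −0.64; −0.40 and −0.75), glutamate receptors for 20 of 22 (median −0.57; −0.41 and −0.77) and pan-neuronal markers for 19 of 20 (median −0.54; −0.41 and −0.65). Gabrg3, a GABA receptor subunit, differed by −0.80 (SE 0.40), the glutamate receptor gene Grm7 by −0.87 (SE 0.40) and the calcium channel gene Cacna1d by −0.59 (SE 0.33). Microglia markers were lower for 20 of 20 (median −0.29; −0.68 and 0.16), as in the purine receptor P2ry12 at −0.64 (SE 0.37). Interferon-stimulated genes were higher for 21 of 27 (median 0.46; 0.36 and 0.53), including the tethering factor Bst2 at 1.64 (SE 0.65). In camera the adjusted p was 2.01e-06 for dissociation, 0.000378 for activity-regulated, 3.55e-05 for channel, 0.000505 for GABA receptor, 0.000227 for glutamate receptor, 0.00128 for pan-neuronal, 0.00547 for microglia and 0.00633 for interferon-stimulated genes. All were lost, at adjusted p = 0.869 with an estimated correlation.

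Camera called 16 of 50 lists for risperidone in microglia, 1 higher and 15 lower, and 24 with the replicate block, while fry called 0 (smallest adjusted p = 0.891). Activity-regulated genes alone stayed called with each library left out, at a camera adjusted p of up to 0.00467. Without vehicle replicate 1 dissociation genes had a camera adjusted p of 0.243 and microglia markers were higher at 0.18. Without vehicle replicate 2 the camera adjusted p was 0.866 for channels, 0.889 for GABA receptors, 0.893 for glutamate receptors and 0.583 for pan-neuronal markers, the last 2 then higher. Without risperidone replicate 1 it was 0.126 for channels, 0.309 for GABA receptors and 0.603 for pan-neuronal markers, and without risperidone replicate 2 it was 0.0879 for microglia markers, all by camera. Interferon-stimulated genes were lower, at camera adjusted p 0.286, without vehicle replicate 2 and 0.724 without risperidone replicate 1. The count of lists was 24 without risperidone replicate 1. No member was called over all genes or adjusted over the list alone, and 59 were adjusted over the list alone with the replicate block.

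Clozapine and risperidone microglia were compared directly, which sets a 10 mg/kg regimen against a 1 mg/kg regimen (n = 2 against 2). Klf9 (ENSMUSG00000033863.3, chromosome 19, 23118590 to 23145498), a glucocorticoid-responsive transcription factor, stood at 41.6 and 65.6 CPM with clozapine and 15.3 and 18.3 with risperidone, a difference of 1.53 (SE 0.36; 95% interval 0.75 to 2.30; 1.29 and 1.69 within batches). Trib3, a stress-induced pseudokinase, stood at 0.494 and 0.564 against 6.07 and 4.54 (−3.43, SE 0.64; interval −4.81 to −2.05). Rflnb, a filamin regulator, differed by 1.79 (SE 0.42; interval 0.89 to 2.70). These 3 had an edgeR adjusted p of 0.671. edgeR called 0 genes, with 2425 at an unadjusted p under 0.05, DESeq2 called 1 and the replicate block 2. The blocked calls were the unnamed genes ENSMUSG00002075676.1 (2.67, SE 0.38, blocked edgeR adjusted p = 7.21e-05) and ENSMUSG00000119584.1 (1.34, SE 0.30, blocked edgeR adjusted p = 0.0261). The first lies on chromosome 12 (69407953 to 69408032). The second, on chromosome 17 (40157244 to 40159092), stood at 16229 and 13692 CPM with clozapine and 5377 and 5358 with risperidone. It was also the most abundant gene in replicate 2 of each neuron group. Neither had a biotype in the annotation used, so the kind of RNA is not known here. RNA left by the ribosomal RNA removal was not examined. The count was 4 without microglia clozapine replicate 1. The median half-width of the 95% interval was 0.71 among genes at a mean log2 CPM of 5 or more, so smaller differences between the regimens stay possible.

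Between the drugs, oxidative phosphorylation genes were higher with clozapine for 31 of 31 members (median 0.55; 0.27 and 0.82 within batches), with Ndufb9 at 1.31 (SE 0.44). Postsynaptic scaffold genes were higher for 21 of 21 (median 0.70; 0.33 and 0.94), as in Shank1 at 1.11 (SE 0.37), and presynaptic release genes for 21 of 21 (median 0.84; 0.48 and 1.00), as in complexin Cplx2 at 1.34 (SE 0.47). Pan-neuronal markers were higher for 20 of 20 (median 0.79; 0.39 and 0.98). Camera called 23 of 50 lists, 22 higher and 1 lower, 29 with the replicate block and 0 with fry (smallest adjusted p = 0.302). Camera adjusted p was 6.53e-11 for oxidative phosphorylation, 8.21e-09 for postsynaptic, 3.57e-07 for presynaptic and 6.55e-06 for pan-neuronal genes, each lost at adjusted p = 0.844 with an estimated correlation. Without clozapine replicate 2 the camera adjusted p was 0.0522 for postsynaptic, 0.526 for presynaptic and 0.865 for pan-neuronal genes. Oxidative phosphorylation and 3 other lists stayed called with each library left out. Adjusted over the list alone 4 members were called, and 88 with the replicate block.

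Clozapine was compared with vehicle in astrocytes (n = 2 against 2), asking which genes respond in this fraction. Itm2a, a membrane protein of endothelial cells, stood at 10.1 and 17.7 CPM against 2.08 and 3.93, a difference of 2.09 (SE 0.59; 2.12 and 1.95 within batches). Ifi27l2a, an interferon-induced gene, stood at 9.56 and 12 against 3.05 and 2.71 (1.81, SE 0.55; 1.54 and 1.90). Mrps24, a mitochondrial ribosomal protein, stood at 22.1 and 17.8 against 5.61 and 6.64 (1.61, SE 0.45). Rab7b, a lysosomal GTPase, stood at 4.85 and 7.73 against 14.1 and 20.6 (−1.56, SE 0.50), and the annexin Anxa4 at 4.85 and 4.22 against 11.2 and 14.1 (−1.58, SE 0.48). The edgeR adjusted p of all 5 was 1. edgeR called 0 genes, with 388 at an unadjusted p under 0.05, and DESeq2 also 0. The replicate block called 4, including the immune inhibitory receptor Lilr4b, which fell by 3.48 (blocked edgeR adjusted p = 0.0019; −4.12, SE 1.67, unblocked), and the RNA-binding gene Rbm47, which fell by 2.24 (0.0161; −2.48, SE 0.79, unblocked). Lilr4b stood at 124 CPM in vehicle replicate 2 and at 2.56 in vehicle replicate 1, and without replicate 2 its difference was 0.59. Rbm47 stood at 35.2 CPM in vehicle replicate 2 and 7.69 in vehicle replicate 1, against 90.5 to 136 in the microglia libraries, and without vehicle replicate 2 its difference was −0.92.

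In clozapine astrocytes oxidative phosphorylation genes were higher for 31 of 31 members (median 0.48; 0.32 and 0.74 within batches), as in Ndufa4 at 1.10 (SE 0.46). Neuronal groups were higher as well: presynaptic release genes for 21 of 21 (median 0.62; 0.20 and 1.24), with the vesicle GTPase Rab3a at 1.17 (SE 0.43), and pan-neuronal markers for 20 of 20 (median 0.54; 0.20 and 0.99), with the tubulin Tubb3 at 0.77 (SE 0.37). Endothelial markers were higher for 15 of 20 (median 0.38; 0.09 and 0.33), with Ptprb at 0.87 (SE 0.35). NF-kB targets and cytokines were lower for 24 of 25 (median −1.17; 0.73 and −2.00), with Tnf at −3.08 (SE 1.13), and microglia markers had a median of −0.38 (0.82 and −1.33). Camera adjusted p was 1.09e-09 for oxidative phosphorylation, 6.1e-09 for presynaptic, 1.8e-08 for pan-neuronal and 0.000157 for endothelial genes, each lost at adjusted p = 0.743 with an estimated correlation. It was 0.000157 for NF-kB targets and 0.0368 for microglia markers, each lost at adjusted p = 0.775 with an estimated correlation. Without vehicle replicate 2, NF-kB targets were higher at a camera adjusted p of 9.94e-10 and microglia markers higher at 0.0119; the latter were higher at 0.171 without clozapine replicate 2, and lower at 0.0953 and 0.0785 without risperidone replicate 1 and 2. Oxidative phosphorylation and presynaptic genes had camera adjusted p of 0.369 and 0.154 without vehicle replicate 2. Striatal projection neuron markers were lower for 14 of 16 (median −0.36; −0.57 and −0.19), at a camera adjusted p of 0.0337 and adjusted p = 0.743 with an estimated correlation. That call was lost with each of the 6 libraries left out, at camera adjusted p from 0.0535 without risperidone replicate 1 to 0.383 without vehicle replicate 1.

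Camera called 24 of 50 lists for clozapine in astrocytes, 20 higher and 4 lower, 29 with the replicate block and 0 with fry (smallest adjusted p = 0.293). Pan-neuronal and endothelial markers stayed called with each library left out, at camera adjusted p up to 0.0297 and 0.0344. The count was 11 without vehicle replicate 2. No member was called over all genes or adjusted over the list alone, and 20 were adjusted over the list alone with the replicate block.

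Risperidone was compared with vehicle in astrocytes to find its targets there (n = 2 against 2). Clca3a1 (ENSMUSG00000056025.13, chromosome 3, 144435438 to 144466738), which modulates chloride channels, stood at 1.64 and 3.63 CPM against 38.3 and 9.35, a difference of −3.16 (SE 0.68; −4.38 and −1.30 within batches). Vtn, a matrix protein of mural cells, stood at 18 and 12.3 against 53.4 and 30 (−1.47, SE 0.43), and Cebpd, an inflammatory transcription factor, at 2.58 and 5.66 against 14.9 and 10.6 (−1.63, SE 0.49). Atp6v0c, a proton pump subunit, stood at 58.6 and 44.6 against 17.5 and 24.1 (1.27, SE 0.36), and the haemoglobin gene Hbb-bt at 76.5 and 91.2 against 23.2 and 40.1 (1.38, SE 0.40). Their edgeR adjusted p was 1. edgeR called 0 genes, with 200 at an unadjusted p under 0.05, and DESeq2 0. The replicate block called 4, among them Clca3a1, which fell by 3.16 (blocked edgeR adjusted p = 0.00299), and the 7S RNA gene Rn7s6, which rose by 1.84 (0.0417) and overlaps another of the 4. Without astrocyte vehicle replicate 2 edgeR called 1 gene, Clca3a1, at an adjusted p of 0.00274.

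Ribosomal protein genes were higher in risperidone astrocytes for 33 of 33 members (median 0.58; 0.68 and 0.16 within batches), as in Rps2 at 0.81 (SE 0.46). Astrocyte markers were higher for 20 of 20 (median 0.43; 0.77 and −0.01), with the neurotensin receptor Ntsr2 at 0.82 (SE 0.48). Cholesterol biosynthesis genes were higher for 22 of 25 (median 0.33; 0.40 and 0.15), with farnesyl diphosphate synthase Fdps at 0.75 (SE 0.34), and oxidative phosphorylation genes for 29 of 31 (median 0.30; 0.38 and 0.14), with Cox5a at 0.54 (SE 0.40). Striatal projection neuron markers were lower for 13 of 16 (median −0.40; −0.50 and −0.20), with the enkephalin gene Penk at −0.51 (SE 0.39). Microglia markers (median 0.15; 0.73 and −0.21) and lysosome genes (0.21; 0.61 and −0.09) were called higher, each at a camera adjusted p of 0.00346 and adjusted p = 0.97 with an estimated correlation. Both were lower without vehicle replicate 1, at camera adjusted p of 0.164 and 0.935, and without risperidone replicate 2 it was 0.0963 and 0.0714. The test by camera gave adjusted p of 5.45e-06 for ribosomal, 0.00118 for astrocyte, cholesterol and oxidative phosphorylation, and 0.00956 for striatal genes, each lost at adjusted p = 0.97 with an estimated correlation. When vehicle replicate 2 was left out the camera adjusted p was 0.36 for ribosomal and 0.187 for oxidative phosphorylation genes, both then lower, 0.276 for astrocyte markers and 0.513 for cholesterol genes. Without risperidone replicate 1 ribosomal and oxidative phosphorylation genes were lower, at camera adjusted p of 0.000235 and 0.00201. Striatal markers had a camera adjusted p of 0.157 and 0.0503 without vehicle replicate 1 and 2, and 0.0713 and 0.116 without risperidone replicate 1 and 2.

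Camera called 10 of 50 lists for risperidone in astrocytes, 9 higher and 1 lower, 12 with the replicate block and 0 with fry (smallest adjusted p = 0.987). None stayed called with each library left out. The count was 24 without vehicle replicate 1, 17 without risperidone replicate 1 and 20 without risperidone replicate 2. Adjusted over the list alone 1 member was called, and 5 with the replicate block.

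The 2 regimens were compared in astrocytes as well (n = 2 against 2). Clca3a1 was 13.7 and 26.8 CPM with clozapine and 1.64 and 3.63 with risperidone, a difference of 2.87 (SE 0.68; interval 1.38 to 4.35; 2.89 and 2.64 within batches). Frzb, a secreted Wnt inhibitor, was 21.3 and 33.7 against 6.21 and 7.4 (1.94, SE 0.42; interval 1.02 to 2.85; 1.75 and 1.99). Ifit3, an interferon-induced gene, was 13 and 18 against 2.58 and 4.5 (2.05, SE 0.49; interval 0.97 to 3.13; 2.24 and 1.79). The edgeR adjusted p of each was 1 unblocked, and with the replicate block 0.00465 for Clca3a1, 0.0204 for Frzb and 0.0501 for Ifit3. edgeR called 0 genes, with 330 at an unadjusted p under 0.05, DESeq2 0 and the replicate block 10, 6 higher and 4 lower with clozapine. The count was 3 without vehicle replicate 2 and 1 without risperidone replicate 2. The median half-width of the 95% interval was 0.89 among genes at a mean log2 CPM of 5 or more.

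Between the drugs in astrocytes, pan-neuronal markers were higher with clozapine for 20 of 20 (median 0.54; 0.16 and 1.22 within batches), with the neurite gene Stmn2 at 1.01 (SE 0.41), and presynaptic release genes for 20 of 21 (median 0.55; 0.14 and 1.29), with the fusion factor Napb at 1.05 (SE 0.48). Microglia markers were lower for 20 of 20 (median −0.47; −0.06 in batch 1 and lower still in batch 2), with the selectin ligand Selplg at −1.19 (SE 0.46). Interferon-stimulated genes had a median of −0.07 but a mean of 0.20, and camera called them higher (adjusted p = 0.0238; adjusted p = 0.795 with an estimated correlation). Camera called 22 of 50 lists, 13 higher and 9 lower, 24 with the replicate block and 0 with fry (smallest adjusted p = 0.635). With camera the adjusted p was 1.35e-08 for pan-neuronal and presynaptic genes and 6.13e-08 for microglia markers, each lost at adjusted p = 0.782 with an estimated correlation. Without risperidone replicate 2 the camera adjusted p was 0.283 for pan-neuronal and 0.781 for presynaptic genes, and without clozapine replicate 2 it was 0.301 for microglia markers and 0.158 for interferon-stimulated genes, which had 0.284 without risperidone replicate 1. None of the 22 stayed called with each library left out. Adjusted over the list alone 3 members were called, and 32 with the replicate block.

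Neurons of clozapine and vehicle animals were compared to find genes that respond in this fraction (n = 2 against 2). Gm36264 (ENSMUSG00000113543.3, chromosome 13, 9051468 to 9126487) stood at 36.9 and 4.19 CPM against 1290 and 263, a difference of −5.24 (SE 0.99), and with the replicate block it fell by 5.39 (edgeR adjusted p = 0.0251). Fndc7, a fibronectin-domain gene, stood at 0.476 and 0.698 against 5.36 and 8.29 (−3.52, SE 0.73). Sp8, an interneuron transcription factor, differed by 1.49 (SE 0.49), Cabp7, a calcium-binding protein, by 1.27 (SE 0.42), and Mrps21, a mitochondrial ribosomal protein, by 0.97 (SE 0.33). The unblocked edgeR adjusted p of these genes was 1. edgeR called 0 genes, with 716 at an unadjusted p under 0.05, against 1 with the replicate block and 20 in DESeq2. The DESeq2 calls included Zmynd15 (−5.20, DESeq2 adjusted p = 6.91e-05), which stood at 46.7 CPM in vehicle replicate 2 and at 5.53 in vehicle replicate 1. edgeR called 266 genes without neuron vehicle replicate 1, 13 without vehicle replicate 2, and 1 and 3 without risperidone replicate 1 and 2.

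In clozapine neurons ribosomal protein genes were higher for 32 of 33 members (median 0.44; 0.54 and 0.32 within batches), as in Rps7 at 0.72 (SE 0.36), and oxidative phosphorylation genes for 30 of 31 (median 0.28; 0.38 and 0.35), as in Ndufb8 at 0.56 (SE 0.34). Mural cell and fibroblast markers were lower for 13 of 16 (median −0.78; −0.67 and −1.06), with the collagen Col1a1 at −2.00 (SE 0.44), and erythrocyte genes for 7 of 7 (median −1.39; −0.94 and −1.13), with Hbb-bs at −1.73 (SE 0.71). NF-kB targets and cytokines were lower for 24 of 24, at a median of −3.12, but the within-batch medians were 0.42 and −4.33, as in Tnf at 5.72 and 0.997 CPM against 4.39 and 158. Neuronal groups were called higher too: pan-neuronal markers (median 0.21; 0.44 and 0.15), glutamatergic (0.33), GABAergic (0.09), presynaptic (0.25) and postsynaptic genes (0.34), at camera adjusted p of 0.0155, 0.00175, 0.0277, 0.00827 and 0.00123, each lost at adjusted p of 0.809 or 0.886 with an estimated correlation. Without vehicle replicate 1 their camera adjusted p was 0.344 (lower), 0.797, 0.021 (lower), 0.919 and 0.427, and without clozapine replicate 2 it was 0.82, 0.272, 0.272 (lower), 0.651 and 0.176. Microglia markers followed NF-kB targets (median −1.25; 1.25 and −3.67), with Cx3cr1 at 17.9 and 5.78 CPM against 8.29 and 79.8. Camera adjusted p was 6.53e-10 for ribosomal, 8.65e-07 for oxidative phosphorylation, 1.97e-05 for mural, 0.000241 for erythrocyte and 7.21e-14 for NF-kB genes, each lost at adjusted p = 0.744 with an estimated correlation. Microglia markers had a camera adjusted p of 3.26e-07, and adjusted p = 0.776 with an estimated correlation. Without vehicle replicate 2, NF-kB targets were higher at a camera adjusted p of 0.344, microglia markers were higher at 0.0408, and Cx3cr1 read 0.54 instead of −1.93. Without clozapine replicate 2 microglia markers had a camera adjusted p of 0.795.

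Camera called 23 of 50 lists for clozapine in neurons, 7 higher and 16 lower, 24 with the replicate block and 0 with fry (smallest adjusted p = 0.537). None of the 23 stayed called with an estimated correlation. Border macrophage markers were low, at a mean log2 CPM of 1.48 and 1.33 with vehicle and 0.48 and 0.60 with clozapine. They stayed called with each library left out, as did ribosomal, oxidative phosphorylation, mural and erythrocyte genes. Without clozapine replicate 2 the count was 15. No member was called over all genes; adjusted over the list alone 21 were, 17 of them NF-kB targets, against 17 in all and 3 NF-kB targets with the replicate block.

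Neurons were compared between risperidone and vehicle, asking which genes respond to this regimen (n = 2 against 2). Usmg5 (ENSMUSG00000071528.5, chromosome 19, 47071903 to 47079086), a small ATP synthase subunit, stood at 18.8 and 22 CPM against 46.5 and 37.8, a difference of −1.03 (SE 0.32; −1.23 and −0.81 within batches). Txnip stood at 5.92 and 10.3 against 18.5 and 32.4 (−1.64, SE 0.42; −1.54 and −1.67). Sash1, a signalling scaffold, stood at 438 and 1241 against 159 and 168 (2.36, SE 0.57; 1.53 and 2.84), and Spred3, an inhibitor of MAP kinase signalling, at 121 and 144 against 65.7 and 63.5 (1.05, SE 0.35; 0.95 and 1.14). Gm36264 stood at 4.14 and 5 against 1290 and 263 (−7.38, SE 1.11; edgeR adjusted p = 0.793), and with the replicate block it fell by 6.81 (edgeR adjusted p = 0.00639). The edgeR adjusted p of Usmg5, Txnip, Sash1 and Spred3 was 1. edgeR called 0 genes, with 204 at an unadjusted p under 0.05, against 1 with the replicate block and 7 in DESeq2, where Sash1 rose by 2.39 (DESeq2 adjusted p = 0.00305). edgeR called 145 genes without neuron vehicle replicate 1, 20 without vehicle replicate 2, and 1 without clozapine replicate 1 or 2.

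Ribosomal protein genes were lower in risperidone neurons for 30 of 33 members (median −0.33; −0.63 and −0.04 within batches), with Rplp0 at −0.81 (SE 0.33), and oxidative phosphorylation genes for 26 of 31 (median −0.19; −0.37 and −0.12), with Cox7c at −0.88 (SE 0.33). Dissociation response genes were lower for 21 of 26 (median −0.69; −0.46 and −0.54), NF-kB targets for 22 of 24 (median −1.69; 0.53 and −2.03), with the subunit Relb at −1.60 (SE 0.54), and microglia markers for 20 of 20 (median −0.97; 0.76 and −1.56). The adjusted p from camera was 7.55e-07 for ribosomal, 0.000112 for oxidative phosphorylation, 0.000309 for dissociation, 0.00145 for NF-kB and 0.00699 for microglia genes, each lost at adjusted p = 0.947 with an estimated correlation. Without risperidone replicate 1 the camera adjusted p was 0.285 for ribosomal genes and 0.608 for oxidative phosphorylation genes, then higher. Without vehicle replicate 1 it was 0.0634 for ribosomal genes, and without vehicle replicate 2 0.105 for oxidative phosphorylation genes. Without vehicle replicate 2, NF-kB targets and microglia markers were higher, at camera adjusted p of 5.64e-16 and 6.75e-10, and dissociation genes higher at 0.0269. Without risperidone replicate 1 the camera adjusted p was 0.737 for NF-kB targets, 0.353 for microglia markers and 0.0778 for dissociation genes.

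Camera called 8 of 50 lists for risperidone in neurons, 1 higher and 7 lower, and 8 with the replicate block, of which 7 were shared; fry called 0 (smallest adjusted p = 0.971). None stayed called with each library left out. The count was 24 without vehicle replicate 1, 30 without vehicle replicate 2, 21 without risperidone replicate 1 and 27 without risperidone replicate 2. Homeostatic microglia genes were lower (median −0.99; 0.55 and −1.56) at a camera adjusted p of 0.0302, lost with the replicate block (0.0635) and with an estimated correlation (0.947). No member was called over all genes or adjusted over the list alone, and 2 were adjusted over the list alone with the replicate block.

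Clozapine and risperidone neurons were compared directly (n = 2 against 2). Ribosomal protein genes were higher with clozapine for 33 of 33 members (median 0.79; 1.16 and 0.36 within batches), with Rpl19 at 1.13 (SE 0.38). Oxidative phosphorylation genes were higher for 31 of 31 (median 0.56; 0.86 and 0.39), with Cox7c at 1.06 (SE 0.33) and Ndufa2 at 0.93 (SE 0.31). Usmg5 was 61.3 and 51.6 against 18.8 and 22 (1.44, SE 0.32; interval 0.75 to 2.14; 1.65 and 1.22), Sp8 differed by 2.33 (SE 0.51; interval 1.21 to 3.46) and Fndc7 by −3.13 (SE 0.73; interval −4.72 to −1.54), each with an edgeR adjusted p of 1. Camera adjusted p was 6.45e-23 for ribosomal and 1.78e-15 for oxidative phosphorylation genes, each lost at adjusted p = 0.782 with an estimated correlation. Both stayed called with each library left out. Gene length and expression level were not tested as a source for ribosomal genes, or for either list between drugs. The mean length of counted genes was 7281 and 7516 bp in clozapine neurons and 7668 and 7723 bp in risperidone neurons. Camera called 15 of 50 lists, 4 higher and 11 lower, 17 with the replicate block, of which 14 were shared, and 0 with fry (smallest adjusted p = 0.821). The call not shared was microglia markers, lower (median −0.29, and 0.65 and −1.99 within batches) at a camera adjusted p of 0.0247 and 0.0798 with the replicate block. It was also lost with an estimated correlation, where the smallest camera adjusted p of any list was 0.782. Adjusted over the list alone 2 members were called, and 35 with the replicate block, 18 of them ribosomal and 10 of oxidative phosphorylation. edgeR called 0 genes, with 831 at an unadjusted p under 0.05, as did the replicate block and DESeq2; it called 58 without vehicle replicate 1 and 15 without vehicle replicate 2. The median half-width of the 95% interval was 0.81 among genes at a mean log2 CPM of 5 or more.

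**Figure D3:**
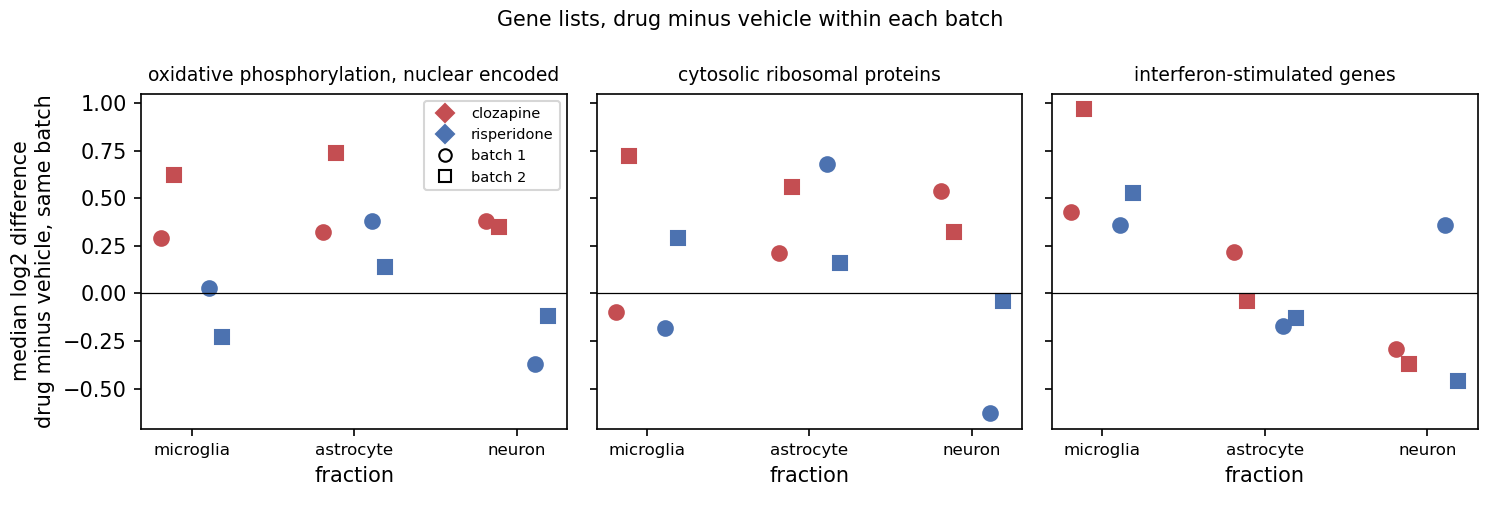
Median log2 differences within each batch for oxidative phosphorylation, ribosomal protein and interferon-stimulated genes. Oxidative phosphorylation medians for clozapine against vehicle were 0.29 and 0.62 in microglia, 0.32 and 0.74 in astrocytes and 0.38 and 0.35 in neurons. Random lists matched on gene length and expression had medians of 0.17, 0.31 and 0.23 over both batches, against 0.46, 0.48 and 0.28.

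Whether a drug acts differently between fractions was tested as the difference of its log2 changes in 1 fit of all 18 libraries. Gm36264 differed between astrocytes and neurons after risperidone by 8.81 (SE 1.25; 9.90 and 6.01 within batches), as it stood at 44.4 and 5.95 CPM in risperidone astrocytes and 12.7 and 4.47 in vehicle astrocytes while falling in neurons from 1290 and 263 to 4.14 and 5. edgeR called it at adjusted p = 0.0136, and 0.00273 with the replicate block. It was the only gene called among the 6 interactions, and DESeq2 called 2 there. The 3 fractions of a pool come from the same cortices, and with each pool as a block, a test chosen after values were seen, Gm36264 differed by 8.30 (SE 1.14, edgeR adjusted p = 0.00955) and was again the only gene called. The edgeR count was 0 without astrocyte vehicle replicate 2 or either neuron risperidone replicate and 6 without astrocyte risperidone replicate 2. Vmn1r55, a vomeronasal receptor gene, differed in the same interaction by 6.13 (SE 1.26, edgeR adjusted p = 0.849). For clozapine, microglia and neurons differed by 5.47 (SE 1.28) in Gpr132, a lysophospholipid receptor, and microglia and astrocytes by 2.29 (SE 0.62) in Rab7b, each with an edgeR adjusted p of 1. For risperidone, microglia and astrocytes differed by 2.81 (SE 0.81) in Fap, a fibroblast protease, and microglia and neurons by −2.20 (SE 0.66) in Zfp711, a zinc finger protein, again with an edgeR adjusted p of 1.

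The other 5 interactions had 0 genes called by edgeR, with unadjusted p under 0.05 for 364 genes (clozapine, microglia against astrocytes), 1480 (clozapine, microglia against neurons), 872 (clozapine, astrocytes against neurons), 483 (risperidone, microglia against astrocytes) and 649 (risperidone, microglia against neurons). With each pool as a block edgeR also called 0 in these 5, with 171, 872, 493, 274 and 386 genes at an unadjusted p under 0.05. DESeq2 called 1 in the risperidone comparison of microglia and neurons. edgeR called 1 gene in clozapine microglia against neurons without astrocyte risperidone replicate 1 or neuron vehicle replicate 1. It called 1 in risperidone microglia against neurons without either astrocyte risperidone replicate or without neuron vehicle replicate 1. In simulated data 14.9% of 67 genes with a 4-fold difference between the clozapine responses of microglia and neurons were recovered, among 34279 genes tested. These 67 genes lay at a mean of 8 CPM or more, so an absent call leaves such differences open.

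Finally the log2 changes of the drugs were correlated within each fraction to ask how much they share. The Pearson correlation across genes was 0.34 in microglia, 0.48 in astrocytes and 0.25 in neurons, and the Spearman correlation 0.28, 0.51 and 0.26. The drugs share their vehicle libraries, and libraries simulated without any drug effect gave 0.49, 0.51 and 0.51 by Pearson and 0.47, 0.47 and 0.46 by Spearman. The measured values lay below these, except the Spearman value in astrocytes. Among genes at a mean log2 CPM of 5 or more, Pearson was 0.50, 0.34 and 0.55 and Spearman 0.46, 0.30 and 0.07, against simulated values of 0.50 by Pearson and 0.48 by Spearman in each fraction. In neurons the Pearson value was then above the highest simulated, 0.53, and the Spearman value below the lowest, 0.46. Without vehicle replicate 1 the Pearson correlation was 0.67 in microglia (0.71 simulated) and 0.65 in neurons (0.72). Without vehicle replicate 2 it was 0.65 in microglia (0.73 simulated) and 0.83 in astrocytes (0.75). It fell to 0.16 in microglia without clozapine replicate 1 (0.38 simulated), 0.24 in astrocytes without risperidone replicate 1 (0.37) and 0.04 in neurons without risperidone replicate 2 (0.37). In 3 of 18 such settings it lay above the highest simulated value: astrocytes without vehicle replicate 2 (highest 0.76), astrocytes without risperidone replicate 2, at 0.44 (0.41), and neurons without risperidone replicate 1, at 0.43 (0.41). The simulated libraries carry no batch difference, which enters the drug contrasts once a library is left out, so these settings do not show more or less sharing than chance. In a test chosen after values were seen, the within-batch change of 1 drug was set against that of the other drug in the other batch, so that no library was on both sides. With clozapine from batch 1 and from batch 2 the Pearson correlation was then −0.06 and −0.04 in microglia, 0.01 and 0.20 in astrocytes, and 0.06 and −0.08 in neurons. Between batches a drug correlated little with itself, at 0.02, 0.06 and 0.09 for clozapine and 0.15, 0.01 and −0.01 for risperidone in the 3 fractions, so these values do not show how much the drugs share.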

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

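The interaction test that brought Gm36264 here was planned, while the pool block and the look at its levels library by library and at Vmn1r55 were chosen after the result was seen. Gm36264 is here because the risperidone difference itself, tested between the astrocyte and neuron fractions, was called: 8.81 log2 (SE 1.25, edgeR adjusted p = 0.0136, 0.00273 with the replicate block and 0.00955 with each pool as a block). In neurons it stood at 1290 and 263 CPM with vehicle, 36.9 and 4.19 with clozapine and 4.14 and 5 with risperidone. In astrocytes it stood at 12.7 and 4.47, 12.8 and 10.1, and 44.4 and 5.95, and in microglia at 14.2 and 20.3, 7.16 and 8.45, and 3.18 and 2.87.

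The difference could be a loss of this RNA in drug-treated neurons or an excess particular to the vehicle neuron pools. The within-batch values, 9.90 and 6.01, have the same sign, so 1 batch alone does not carry it. The call is absent without astrocyte vehicle replicate 2 or either neuron risperidone replicate, where edgeR called 0 genes, and edgeR called 6 without astrocyte risperidone replicate 2. Vmn1r55, a vomeronasal receptor gene on chromosome 7, was also high in vehicle neurons, at 252 and 109 CPM against 2.98 and 13.7 with clozapine and 30.8 and 4.56 with risperidone, and its risperidone difference between astrocytes and neurons was 6.13 (SE 1.26, edgeR adjusted p = 0.849). The cause was not tested, and with 2 vehicle pools a property of those pools and an action of the drugs cannot be told apart.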

How the results depend on the processing

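The alternatives here were planned, except the marker covariate, the pool block, the correlations with separate vehicle pools and the leave-1-out tests of single lists, which are tests chosen after the result was seen. Of 3619 alternative values for 293 gene results, 3412 kept their direction and stayed called or uncalled as in the main fit. Of the others 2 lost a call, 184 gained 1 and 21 turned in sign, all 21 with a library left out. The main fit called 0 genes in every drug comparison within a fraction, so those results could only stay uncalled or gain a call. These counts do not show how far the estimates moved. The replicate block raised calls from 0 to 5 for clozapine in microglia and from 0 to 2 between drugs there. In astrocytes it raised them from 0 to 4 for clozapine, 4 for risperidone and 10 between drugs, and in neurons from 0 to 1 for each drug. Between vehicle fractions it gave 1446 instead of 715 for microglia and astrocytes, 2988 instead of 1810 for microglia and neurons, and 64 instead of 1 for astrocytes and neurons. It also changed the counts of lists and the list calls given in the report. DESeq2 called 1 gene for clozapine and 1 between drugs in microglia, 20 for clozapine and 7 for risperidone in neurons, 1349, 3143 and 490 between fractions, and 1 and 2 in the risperidone interactions of microglia and of astrocytes with neurons. RLE scaling kept 0 in every drug comparison, as did adjusted p under 0.10, which gave 1345, 3939 and 2 in the comparisons of microglia with astrocytes, microglia with neurons and the risperidone interaction of astrocytes with neurons.

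Without the low-count filter edgeR called 14, 10 and 24 genes in microglia (clozapine, risperidone, between drugs), 52, 4 and 38 in astrocytes and 171, 47 and 61 in neurons. It then called 1466, 3063 and 180 between fractions, 16, 173 and 21 in the clozapine interactions and 4, 9 and 11 in the risperidone interactions. Fitting all 18 libraries together gave 1 for risperidone in neurons, and the marker covariate gave 1 between drugs in microglia. With each pool as a block the 6 interactions kept their counts, 1 for risperidone between astrocytes and neurons and 0 in the others. With each library left out, edgeR counts ran from 0 to 1 for clozapine and for risperidone and from 0 to 4 between drugs in microglia, from 0 to 1 for risperidone and 0 to 3 between drugs in astrocytes, and in neurons from 0 to 266, 0 to 145 and 0 to 58. They ran from 97 to 1459, 616 to 3375 and 5 to 1100 between fractions, from 0 to 1 in the interactions of microglia and neurons for each drug, and from 0 to 6 in the risperidone interaction of astrocytes and neurons.

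Camera called 14 lists for clozapine and 16 for risperidone in microglia, 24 and 10 in astrocytes, and 23 and 8 in neurons. With an estimated correlation all 6 counts were 0, and with fry all 6 were 0. With a library left out they ran from 14 to 28 and 13 to 24 in microglia, 11 to 32 and 8 to 24 in astrocytes, and 15 to 29 and 10 to 30 in neurons. These totals include other lists: of those called with all libraries as few as 7 of 14 and 6 of 16 were kept in microglia, 5 of 24 and 2 of 10 in astrocytes, and 11 of 23 and 1 of 8 in neurons. With each library left out in turn, 1, 1, 2, 0, 5 and 0 were kept throughout. The correlation between drugs ran from 0.16 to 0.67 in microglia, 0.24 to 0.83 in astrocytes and 0.04 to 0.65 in neurons, and was 0.55 in neurons among genes at a mean log2 CPM of 5 or more instead of 0.25. With separate vehicle pools it was −0.06 and −0.04 in microglia, 0.01 and 0.20 in astrocytes and 0.06 and −0.08 in neurons.

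When a library was left out, 21 of the 293 gene results turned in sign, 116 others moved by over 1.5 times and 156 did neither. Genes that turned in sign are given with the lowest and highest log2 difference with a library left out, and the value with all libraries. In risperidone microglia Cacng8 ran from −1.02 to 0.00 (−0.57; turned without vehicle replicate 2). In risperidone astrocytes Selplg ran from −0.04 to 1.24 (0.45) and C1qc from −0.10 to 1.36 (0.44), turned without vehicle replicate 1. Without risperidone replicate 1 Aldh1l1 ran from −0.16 to 1.02 (0.53), Mertk from −0.12 to 0.92 (0.48), Ndufb8 from −0.52 to 1.38 (0.70) and Rps23 from −0.34 to 2.02 (1.23). Lilr4b ran from −5.54 to 0.59 (−4.12) for clozapine in astrocytes, turned without vehicle replicate 2, and from −4.74 to 1.63 (−3.33) between drugs, turned without risperidone replicate 2. In clozapine neurons, turned without vehicle replicate 2, Cx3cr1 ran from −2.95 to 0.54 (−1.93), Itgam from −4.01 to 0.17 (−1.77), Csf1r from −3.31 to 0.78 (−1.83), C3ar1 from −5.48 to 1.10 (−4.16), C5ar1 from −4.26 to 0.36 (−3.32) and Cd44 from −4.40 to 0.50 (−3.46). In risperidone neurons, turned without vehicle replicate 2, Ctss ran from −2.56 to 1.28 (−1.64), Atf3 from −1.94 to 0.10 (−1.14), Klf6 from −1.84 to 0.17 (−1.15), Ccl2 from −2.61 to 0.41 (−1.78) and Tlr2 from −3.33 to 1.98 (−2.36). Cers2 ran from −1.32 to 0.05 (−0.78), turned without vehicle replicate 1. The libraries concerned differ from their partners in markers of several cell types or in ribosomal and metabolic genes, and the cause was not tested. Besides microglia markers, pan-neuronal markers stood at 7.16 log2 CPM in microglia vehicle replicate 2 against 5.87 in replicate 1. Astrocyte markers stood at 8.87 in astrocyte risperidone replicate 1 against 7.63 in replicate 2. Oligodendrocyte markers stood at 7.88 in neuron vehicle replicate 1 against 6.76 in replicate 2. Depth of 4.71 to 13.39 M counts and 2 pools per group both limit these results, and their effects were not compared.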

Other observations

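The tests of gene length and expression level and of mRNA localised to myelin were written before their values were seen, and the other tests in this part were chosen after the result was seen. Mbp differed between batches as well as between fractions. It averaged 9900 CPM (SD 10374, n = 6) in astrocytes and 6713 (SD 6029) in neurons, with the higher value in batch 1. The difference of batch 1 minus batch 2, averaged over the 6 pairs of fraction and treatment, was 2.82 log2 for Mbp. Mobp, another gene of compact myelin, differed by 3.02, the ferritin gene Fth1 by 1.50 and Trp53inp2 by 1.74, while Car2 differed by −0.17 and Padi2 by −0.24.

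Mitochondrial features had 0 counts in all 18 libraries, while nuclear copies of mitochondrial sequence had many. Gm28437 on chromosome 1 (24652270 to 24653052) ranged from 37.2 to 873 CPM and Gm28661 (24653966 to 24654646) from 38 to 1330, with the highest values in neuron vehicle replicate 1. These values were looked up after the data were seen, and no test was made of them.

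Mbp and batch. More oligodendrocyte cell bodies in batch 1 would raise other oligodendrocyte markers, but the median over 19 of them was −0.01 (interval −0.17 to 0.30), while the lowest Mbp difference was 1.58, which excludes this explanation. Myelin fragments carrying localised mRNA could raise Mbp and other localised transcripts without most oligodendrocyte markers. The median of the 5 localised transcripts, 1.50, went with that prediction. Car2 and Padi2 at −0.17 and −0.24 are exceptions. A batch difference in library chemistry was not tested, so the source stays open.

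Interferon-stimulated genes in clozapine microglia. Blood leukocytes could carry such transcripts. Their markers lay below the interferon-stimulated genes by −0.97 (interval −1.54 to −0.29) in batch 1 and −1.14 (−2.29 to −0.20) in batch 2, but near the floor of detection, so they exclude nothing. Medians were 0.43 (0.08 to 0.74) and 0.97 (0.32 to 1.64) within batches, both above 0. The rule for this test also asked the call to hold with each library left out, and it was lost without vehicle replicate 2. That fit has no batch term, so the batch difference enters it and the loss cannot decide. With 1 library per treatment in each batch, how much each batch carries stays open. With batch as a term the list mean differed by 0.76 (t interval with 2 residual degrees of freedom −0.37 to 1.89), so chance differences between pools may account for the shift.

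Oxidative phosphorylation genes and clozapine. Gene length or expression level is excluded as the whole cause in microglia, where the median of 0.46 stood at percentile 100 of 1000 matched random lists (their median 0.17, interval 0.03 to 0.31), and in astrocytes, where 0.48 stood at percentile 99.9 (0.31, 0.21 to 0.42), but it stays open for the part these lists share. In neurons percentile 76.9 (0.23, 0.11 to 0.35) leaves it open as a source but does not show that it is one. Neuronal RNA would raise pan-neuronal markers by at least as much, but in microglia their rise minus that of the respiratory genes was −0.20 log2 with batch as a term (the same kind of interval, −0.31 to −0.08). This argues against neuronal RNA as the whole source, although pan-neuronal markers rose in batch 2, from 7.16 to 7.57 log2 CPM. In astrocytes that difference, 0.02 (−0.46 to 0.51), leaves it open. In microglia batch 1 astrocyte markers rose from 6.09 to 6.88 and oligodendrocyte markers from 4.89 to 6.20. In batch 2 they went from 5.66 to 5.87 and from 5.13 to 4.94. RNA of these cells, or a mixture that differs between batches, was not tested as a source. A shift in respiratory genes of microglia stays a hypothesis. Camera with an estimated correlation (adjusted p = 0.994) cannot decide, as it missed a simulated 1.5-fold rise of this list. Fry recovered that rise in simulated microglia and called 0 lists here. The simulated genes were independent of each other and carried no batch difference, so fry cannot decide either.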
